A study of Homo sapiens with 18 samples.

How the data were processed

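RNA sequencing was run on 18 libraries of the cell line HAIR-M, 3 for each of 6 groups: DMSO or 5 nM copanlisib for 4, 8 or 12 h. Group, time and replicate number came from the labels of each sample. The authors deposited 1 table of read counts per gene and library, as raw counts with no normalization, which the values bear out: whole numbers with a different total in each library. Reads were handled with CASAVA 1.7 and aligned to hg38 with STAR 2.5.2b, per the submitters' processing notes, which also fit the layout of the deposited count tables: 60483 gene identifiers, 4 summary lines and 3 columns of counts (without strand and for each strand). The annotation version is not given in the sources used here. The labels' protocols speak of retinas, which goes against the cell line named in the labels, so a list of retina markers was fixed before the data were examined. Names came from a gene name table for 41124 identifiers and from GENCODE 29 for 15629, and 3730 stayed without a name. All 598 entries of the gene lists matched an identifier.

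The labels' protocols name a kit that does not mark strand, but in the deposited counts 1 strand column held 94.3% to 95.3% of the reads assigned to a strand in every library. By the rule fixed before the data were examined (more than 80% in 1 strand column), the main counts are that column, and the column without strand is an alternative. The summary lines were left out of library sizes and tests. Per library, 1.74% to 8.73% of the reads were unmapped, 9.21% to 10.1% mapped to several places, 10.0% to 13.0% hit no gene and 2.04% to 2.45% were ambiguous, which left 67.5% to 75.2% as gene reads. Since reads that map to several places were not counted, genes with near-identical copies are undercounted. Gene reads per library ranged from 13587017 to 25566761, and the report gives them for each library. No 2 replicates agreed within sampling noise: the chi-square per gene over genes with at least 20 reads lay between 1.52 and 19.9, where 1 is sampling noise, so all 18 libraries were kept as separate.

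Tests used R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Of 35239 genes with any read, 16122 passed filterByExpr by group, and they held at least 99.87% of the gene reads of each library. The counts were scaled by TMM, and 1 model with a mean per group was fitted to all 18 libraries with glmQLFit. The common biological coefficient of variation was 0.0500 and the median prior degrees of freedom 13.8. Contrasts were tested two-sided with glmQLFTest and adjusted by Benjamini-Hochberg over all genes tested, with an adjusted p under 0.05 as the threshold. The contrasts were copanlisib against DMSO at each time, their average, the difference of the effects between the 3 times and between 12 h and 4 h, and time in DMSO. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM are computed from the counts and the TMM-scaled library sizes, and the levels of marker genes that are given as a highest or lowest value from the plain library sizes.

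Gene lists, 26 in all, were fixed from textbook knowledge before the data were examined. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists within each contrast. Camera with an estimated correlation and fry were run beside it, and members were counted by the test per gene, adjusted over all genes and over the list alone. Lists needed at least 3 tested members. The lists cover FOXO targets, PI3K-AKT-mTOR components, MYC and nucleolar targets, cholesterol synthesis, fatty acid synthesis, glycolysis and hypoxia, ATF4 and the amino acid response, B cell receptor signalling, the immediate early and ERK response, NF-kB targets, G1-S and G2-M genes, the BCL2 family, B cell identity, plasma cell genes, migration receptors, the interferon response, HLA class I and II, cytosolic ribosomal proteins, lysosome and autophagy, p53 targets, and markers of T and NK cells, myeloid cells, stroma and epithelium, and retina.

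The rule for named genes was also fixed before the data were examined. It takes, for each time, the 8 highest and 8 lowest log2 fold changes among protein-coding genes past the threshold with an average log2 CPM of at least 3 and all 3 copanlisib libraries on 1 side of the 3 DMSO libraries. Chance puts 10% of genes in that arrangement of 3 against 3. It adds up to 4 members of each list with the largest changes (or 1 with the smallest p), 16 fixed genes, and the 5 highest and 5 lowest for the difference between 12 h and 4 h and for DMSO over time. This gave 213 genes and 356 results, of which the text uses a part. Antigen receptor segments were left out of the rule's first part.

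Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, no filter on low counts, DESeq2, limma-voom, the counts without strand, the replicate number as a block, only the 6 libraries of a time, an adjusted p under 0.01, a log2 fold change of at least 1, and each library left out in turn. A correction for GC content and transcript length (lowess with a span of 0.3 on log2 CPM with a prior count of 2) and a fit with replicate 3 as the only copanlisib library at 4 h were chosen after the data were seen. In the latter the lone library is assumed to vary like the other groups. Other splits of the samples were 10 for each time and 100 drawn for the other results.

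The procedure was tested on simulated counts with 200 changed genes, 50 for each of 4 fold sizes. The genes were changed at 4 h for the tests of that time, of the average and of differences between times. At the smallest fold edgeR recovered 32 of 50 genes at 4 h, 33 at 8 h, 38 at 12 h, 5 for the average, 20 for the difference between the 3 times, 16 for the difference between 12 h and 4 h and 40 for time in DMSO. At 1.5-fold edgeR recovered 49 of 50 genes at 4 h, 50 at 8 h, 49 at 12 h, 41 for the average, 46 for the difference between the 3 times, 44 for the difference between 12 h and 4 h and 50 for time in DMSO. At 2-fold it recovered 50 of 50 in the comparisons at 4 h, 8 h and 12 h, over time in DMSO and for the difference between the 3 times, and 49 for the average and the difference between 12 h and 4 h. At 4-fold it recovered 50 of 50 in each of the 7 comparisons. False calls numbered 4 to 13 among 15842 to 15875 genes. When a GC trend was simulated in 2 libraries, 1001 genes were called falsely without the correction and 10 with it. Camera at both settings and fry called 5 of 5 shifted sets of 25 genes and 0 of 5 unchanged sets. The simulated genes varied independently of each other, so this does not test camera's p-values for lists whose members are correlated.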

Results

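RNA sequencing measured gene expression in HAIR-M, a human B cell line that the labels class as MZL, marginal zone lymphoma, a lymphoma of mature B cells. The cells received 5 nM copanlisib, an inhibitor of phosphoinositide 3-kinases (PI3K), or its solvent DMSO for 4, 8 or 12 h. This gave 6 groups of 3 libraries, 18 libraries in all, and the DMSO libraries of the same time served as the control of each copanlisib group. The reads counted on genes ranged from 13587017 to 25566761 per library. The 3 DMSO libraries held 14023303, 20230287 and 18869599 gene reads at 4 h, 21583576, 16467953 and 13587017 at 8 h, and 18096610, 16383898 and 19573586 at 12 h. The 3 copanlisib libraries held 20859455, 20667639 and 18724224 at 4 h, 20176516, 23042286 and 25566761 at 8 h, and 18864012, 15741233 and 19025252 at 12 h. Between 22407 and 25380 genes had at least 1 read in a library, and 16122 genes passed the filter on low counts and were tested. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical. Values are given as CPM, reads of a gene scaled to library size, with the SD over 3 libraries, and as log2 fold changes with their standard error (SE).

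Replicates 1 and 2 of copanlisib at 4 h stood apart from the other 16 libraries. Their unmapped reads made up 8.73% and 5.22% of all reads, against 1.74% to 2.82% elsewhere, and mitochondrial genes took 12.4% and 12.6% of their gene reads, against 9.07% to 10.5% elsewhere. Each differed from replicate 3 of its group by a chi-square of 19.9 and 15.8 per gene, where 1 is sampling noise and the other 16 pairs of replicates lay between 1.52 and 2.94. The 4 h log2 fold changes fell with the GC content of the genes: the median was 0.12 in the fifth of genes with the lowest GC content and −0.21 in the fifth with the highest. These medians were −0.04 and 0.00 with replicate 3 as the only copanlisib library. That fit was chosen after the data were seen, and its values stand beside some of the 4 h results that it moved.

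**Figure D1:**
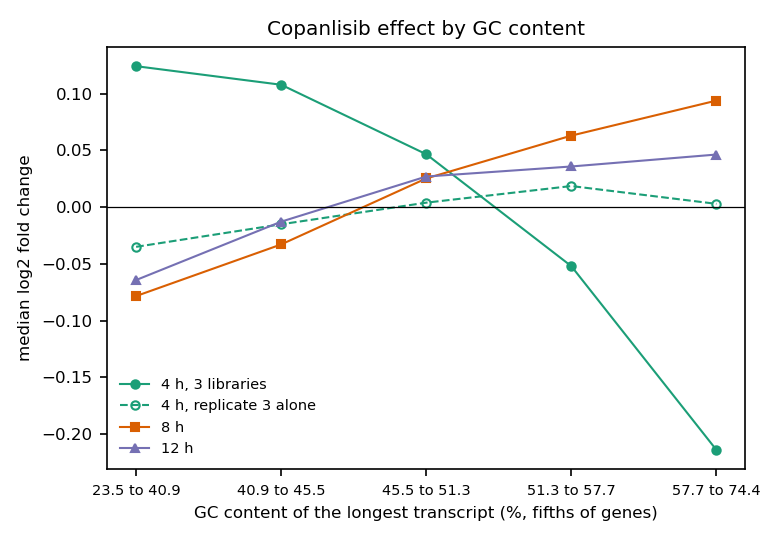
Median log2 fold change (copanlisib against DMSO of the same time, y axis) of the tested genes in 5 classes of equal size by GC content (x axis, %), with 1 line for each of 4 h, 8 h, 12 h and 4 h with replicate 3 as the only copanlisib library. The 4 h line runs from 0.12 to −0.21, the line for replicate 3 alone stays between −0.04 and 0.02, and the 8 h and 12 h lines rise from −0.08 to 0.09 and from −0.06 to 0.05.

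The series asks how PI3K inhibition changes the transcriptome of these lymphoma cells, and the 4 h comparison gives its earliest state here. After 4 h, transcripts of XCL1, the chemokine lymphotactin, were at 18.8 ± 1.2 CPM with copanlisib and 81.3 ± 2.6 CPM with DMSO (SD, n = 3 each). Its log2 fold change was −2.11 ± 0.07 (SE, edgeR adjusted p = 8.8e-17). The immediate early transcription factors EGR3 (−1.84 ± 0.08) and NR4A1 (−1.80 ± 0.08) and the chemokine CCL3 (−2.18 ± 0.11) fell as well. TP53INP1, a stress-induced regulator of autophagy, rose from 70.1 ± 1.9 to 196 ± 11.1 CPM (log2 fold change 1.48 ± 0.06, edgeR adjusted p = 1.7e-16). TP63, a p53 family member, rose by a log2 fold change of 1.24 ± 0.07, and PIK3CG, the catalytic PI3K subunit gamma, rose by 1.23 ± 0.09. By edgeR's quasi-likelihood test, 2860 of the 16122 genes rose and 3335 fell, 6195 in all, of which 352 changed at least 2-fold (173 higher, 179 lower). When replicate 3 was the only copanlisib library, 3778 genes passed, 2931 of them among the 6195. When only the 6 libraries of this time entered the fit, 3733 passed.

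Genes that respond to mitogenic and antigen signals fell together at 4 h. Of 25 measured genes of the immediate early and ERK response, 19 fell, 1 rose and 5 did not pass (19 and 1 adjusted over the list alone), with a median log2 fold change of −0.75 (camera adjusted p = 6.4e-24). EGR1, an immediate early transcription factor, was at 14.5 ± 1.5 CPM against 40.5 ± 3.3 (−1.48 ± 0.09, edgeR adjusted p = 3.7e-12). FOSL1, an AP-1 subunit, fell by 1.80 ± 0.09 on the log2 scale. Of 26 measured NF-kB targets, 22 fell and 1 rose, the same counts as adjusted over the list alone, with a median of −0.50 (camera adjusted p = 5.9e-27). Among them the cytokine TNF fell by 0.92 ± 0.07 and REL, itself an NF-kB subunit, by 0.92 ± 0.10. With replicate 3 as the only copanlisib library, the median was −0.61 for the immediate early and ERK response and −0.44 for NF-kB targets.

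Genes of growth and biosynthesis were lower at 4 h. Of 35 measured MYC and nucleolar targets, 32 fell and 3 did not pass (33 fell adjusted over the list alone), with a median log2 fold change of −0.57 (camera adjusted p = 1.1e-34). MYC, a transcription factor of cell growth, was at 145 ± 2.7 CPM against 235 ± 6.8 (−0.70 ± 0.04, edgeR adjusted p = 6.3e-12). NOP16, a ribosome assembly factor, fell by 1.04 ± 0.06. Of 31 measured genes of ATF4 and the amino acid response, 29 fell and 2 rose, also adjusted over the list alone, with a median of −0.47 (camera adjusted p = 4.9e-28). SLC7A5, which carries large neutral amino acids into cells, was at 96.9 ± 11.8 CPM against 264 ± 9.0 (−1.44 ± 0.06, edgeR adjusted p = 1.9e-15). Of 25 measured genes of cholesterol synthesis, 20 fell and none rose (23 fell adjusted over the list alone, median −0.31, camera adjusted p = 1.7e-12). Among them was HMGCS1, which makes the precursor of mevalonate, at −0.55 ± 0.05. Of 15 measured genes of fatty acid synthesis, 11 fell and 1 rose, also adjusted over the list alone (median −0.27, camera adjusted p = 5.3e-06). The fatty acid synthase gene FASN fell by 1.08 ± 0.10, and its log2 fold change was −0.67 with replicate 3 as the only copanlisib library. Of 25 measured genes of glycolysis and hypoxia, 14 fell and none rose, also adjusted over the list alone (median −0.12, camera adjusted p = 1.6e-05, but adjusted p = 0.27 with an estimated correlation), with HK2, a hexokinase, at −1.02 ± 0.07. Of these glycolysis and hypoxia genes, 9 fell when replicate 3 was the only copanlisib library (camera adjusted p = 9.5e-04, but adjusted p = 0.49 with an estimated correlation).

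FOXO targets rose at 4 h, as did interferon response and G2-M genes. Of 26 measured FOXO targets, genes that FOXO factors switch on when PI3K and AKT are quiet, 18 rose and 1 fell (19 and 1 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 1.1e-13). TXNIP, an inhibitor of thioredoxin and glucose uptake, was at 136 ± 10.0 CPM against 72.6 ± 1.7 (0.91 ± 0.06, edgeR adjusted p = 1.7e-11). PIK3IP1, an inhibitor of PI3K, rose by 0.66 ± 0.10. The median of the FOXO targets was 0.36 with replicate 3 as the only copanlisib library. Of 30 measured interferon response genes, 20 rose and 3 fell (20 and 4 adjusted over the list alone, median 0.26, camera adjusted p = 9.4e-07, but adjusted p = 0.056 with an estimated correlation). IFIT2, an interferon-induced RNA-binding protein, rose by 0.92 ± 0.11, and its log2 fold change was 0.57 with replicate 3 as the only copanlisib library. The median of the interferon response genes was 0.21 in that fit. Of 25 measured G2-M genes, 16 rose and none fell (17 and 2 adjusted over the list alone, median 0.24, camera adjusted p = 9.3e-05, but adjusted p = 0.20 with an estimated correlation). With replicate 3 as the only copanlisib library, 8 of these G2-M genes rose and none fell (camera adjusted p = 0.011, but adjusted p = 0.37 with an estimated correlation), and the spindle gene HMMR went from 0.55 ± 0.09 to 0.27. The other 7 list calls at 4 h held with an estimated correlation, at adjusted p from 6.1e-05 to 0.021, but with replicate 3 as the only copanlisib library fatty acid synthesis did not (adjusted p = 0.072).

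Members of a few other groups moved at 4 h without a call for their list. The chemokine receptor CXCR4 rose by 0.81 ± 0.05 (154 ± 4.0 CPM against 87.8 ± 2.3). BMF, a BH3-only activator of cell death, and MCL1, a survival factor of the BCL2 family, rose by 0.83 ± 0.07 and 0.46 ± 0.05. BCL2L1 and BCL2A1, which also encode survival factors, fell by 0.49 ± 0.04 and 0.57 ± 0.06, while BCL2 itself was at −0.03 ± 0.05 (edgeR adjusted p = 0.64). PTPN6, the phosphatase SHP-1 that restrains antigen receptor signals, fell by 0.80 ± 0.04. Of 12 measured HLA class I genes 7 fell (8 adjusted over the list alone) and of 40 cytosolic ribosomal protein genes 11 fell and 1 rose (8 fell adjusted over the list alone, camera adjusted p = 0.17 and 0.28). When replicate 3 was the only copanlisib library, 1 HLA class I gene rose, 1 fell and none of the ribosomal protein genes passed by edgeR. In that fit the log2 fold changes of HLA-C, HLA-DQB1 and RPL13 went from −0.27, −0.17 and −0.24 to 0.022, 0.0045 and 0.0056. Leaving out only replicate 2 of copanlisib ended the calls of HLA-C, HLA-DQB1 and RPL13 (edgeR adjusted p = 0.056, 0.093 and 0.066), as did leaving out replicate 1 for HLA-DQB1 and RPL13 (0.087 and 0.051). Without replicate 3 of DMSO HLA-DQB1 was lost (0.060), and without replicate 1 of DMSO RPL13 (0.056). Genes of the HLA and ribosomal protein families, XCL1, CCL3, CCL4 and HSPA6 share sequence with near-identical copies, so their read counts are uncertain.

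**Figure D2:**
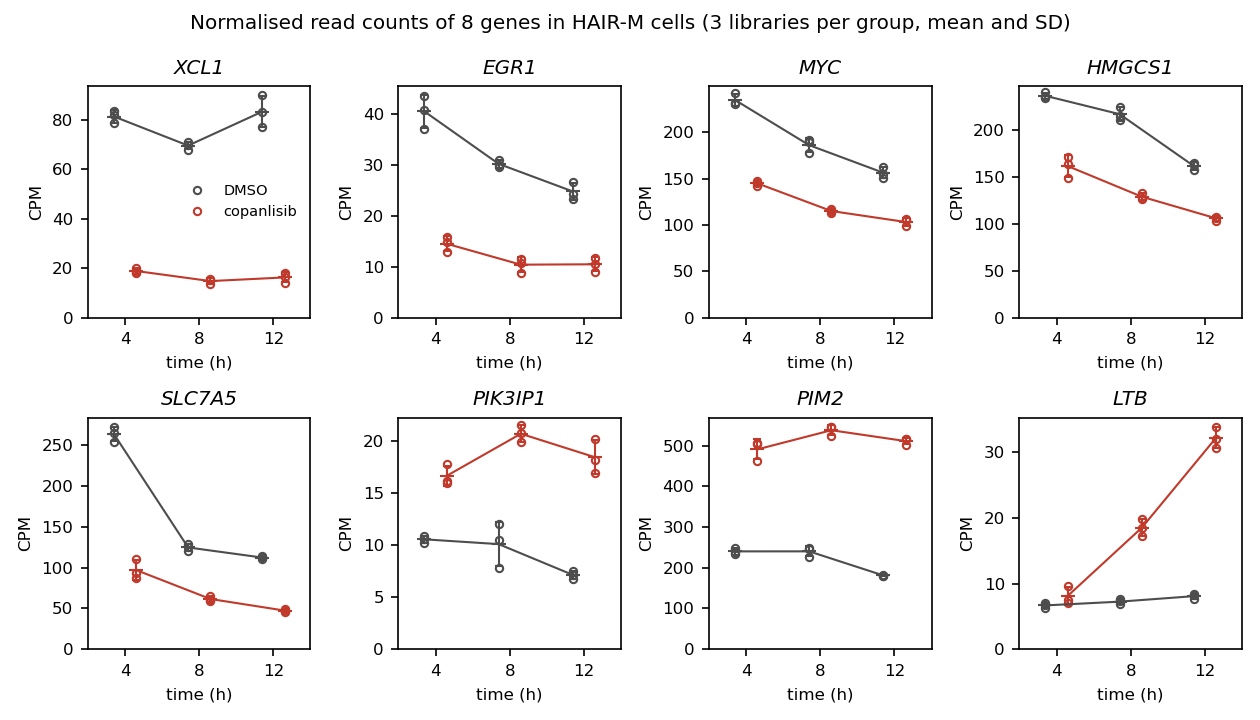
CPM (y axis) of XCL1, EGR1, MYC, HMGCS1, SLC7A5, PIK3IP1, PIM2 and LTB against hours of treatment (x axis) in DMSO and copanlisib libraries, with open circles for the 3 libraries of a group and the mean with its SD. XCL1 stays at 14.8 to 18.8 CPM with copanlisib against 69.5 to 83.3 with DMSO, while LTB with copanlisib reaches 32.2 CPM at 12 h.

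The 8 h comparison asks the same of cells treated for a longer time. PIM2, a serine/threonine kinase that promotes survival of lymphoid cells, rose from 240.2 ± 12.1 to 538 ± 12.7 CPM (SD, n = 3 each), a log2 fold change of 1.16 ± 0.04 (edgeR adjusted p = 3.4e-16). LTB, the cytokine lymphotoxin beta, rose from 7.23 ± 0.39 to 18.5 ± 1.3 CPM (1.36 ± 0.10, edgeR adjusted p = 4.5e-11), and PIK3IP1 by 1.02 ± 0.10. XCL1 was at 14.8 ± 1.1 CPM against 69.5 ± 1.5 (−2.23 ± 0.07, edgeR adjusted p = 3.1e-17), EGR1 at 10.4 ± 1.4 against 30.2 ± 0.7, and POLR3G, a subunit of RNA polymerase III, fell by 1.29 ± 0.09. PUS7, a pseudouridine synthase, and HOMER1, a scaffold protein, fell by 1.31 ± 0.08 and 1.29 ± 0.08. In all, 2392 of the 16122 genes rose and 2944 fell, 5336 in total, of which 235 changed at least 2-fold, 159 higher and 76 lower.

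The growth and biosynthesis lists were lower at 8 h. Each of the 35 measured MYC and nucleolar targets fell, also adjusted over the list alone (median −0.62, camera adjusted p = 1.0e-52). MYC was at −0.69 ± 0.04 and the nucleolar phosphoprotein gene NOLC1 at 178 ± 3.4 CPM against 334 ± 5.5 (−0.90 ± 0.04, edgeR adjusted p = 3.6e-15). In cholesterol synthesis 20 of 25 fell and 1 rose, also adjusted over the list alone (median −0.42, camera adjusted p = 9.4e-17). HMGCS1 was at 129 ± 3.7 CPM against 217 ± 7.2 (−0.75 ± 0.05, edgeR adjusted p = 5.6e-12). In fatty acid synthesis 11 of 15 fell and none rose, also adjusted over the list alone (median −0.37, camera adjusted p = 2.4e-10). SCD, which desaturates fatty acids, fell by 0.82 ± 0.04. Of the 31 genes of ATF4 and the amino acid response, 24 fell and 1 rose, also adjusted over the list alone (median −0.51, camera adjusted p = 2.6e-25). PSAT1 of serine synthesis was at −1.17 ± 0.07 and the asparagine synthetase gene ASNS at −1.01 ± 0.06. In glycolysis and hypoxia 13 of 25 fell and none rose, also adjusted over the list alone (median −0.14, camera adjusted p = 1.4e-05, but adjusted p = 0.26 with an estimated correlation).

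Signal-responsive genes were also lower at 8 h. In the immediate early and ERK response 18 of 25 genes fell and 2 rose (18 and 3 adjusted over the list alone, median −0.53, camera adjusted p = 8.2e-13), with EGR1 at −1.53 ± 0.10 and EGR3 at −1.72 ± 0.09. Of 26 NF-kB targets, 15 fell and 3 rose (16 and 3 adjusted over the list alone, median −0.24, camera adjusted p = 5.2e-06), with CCL3 at −1.73 ± 0.11 among the fallen and LTB among the risen.

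FOXO targets, interferon genes and B cell genes were higher at 8 h. Of 26 FOXO targets, 18 rose and 1 fell, also adjusted over the list alone (median 0.36, camera adjusted p = 4.2e-13). TSC22D3, a leucine zipper regulator, rose from 79.4 ± 1.9 to 157 ± 3.6 CPM (0.98 ± 0.05, edgeR adjusted p = 2.9e-14) and YPEL3 by 1.16 ± 0.07. Of 30 interferon response genes, 15 rose and none fell (17 rose adjusted over the list alone, median 0.19, camera adjusted p = 5.9e-05, but adjusted p = 0.088 with an estimated correlation), with the transcription factor gene STAT2 at 0.44 ± 0.04. Of 19 measured B cell identity genes, 7 rose and 1 fell, also adjusted over the list alone (median 0.09, camera adjusted p = 3.9e-04). TCL1A, an AKT co-activator of B cells, rose from 519 ± 14.8 to 767 ± 14.8 CPM (0.56 ± 0.05, edgeR adjusted p = 6.9e-10). Of 8 measured stromal and epithelial markers, 6 rose and none fell (7 rose adjusted over the list alone, median 0.43, camera adjusted p = 0.0022). They included the collagen gene COL1A1 at 26.0 ± 0.8 CPM against 18.3 ± 1.2 and the keratin gene KRT18 at 27.1 ± 1.5 against 19.9 ± 1.0. The 9 list calls at 8 h other than glycolysis and the interferon response held with an estimated correlation, at adjusted p from 2.0e-05 to 0.042.

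At 12 h, the last time sampled, LTB reached 32.2 ± 1.6 CPM with copanlisib against 8.07 ± 0.38 with DMSO (SD, n = 3 each), a log2 fold change of 2.00 ± 0.09 (edgeR adjusted p = 1.1e-14). PIM2 was at 511 ± 8.3 CPM against 181 ± 1.2 (edgeR adjusted p = 1.8e-18), and MEOX1, a homeobox transcription factor, rose by 1.26 ± 0.10. XCL1 was at 16.2 ± 2.0 CPM against 83.3 ± 6.4 (−2.37 ± 0.08, edgeR adjusted p = 5.1e-18). SLC7A11, which imports cystine, fell from 12.0 ± 1.2 to 4.08 ± 0.24 CPM (−1.55 ± 0.13, edgeR adjusted p = 5.5e-10). CHAC1, which breaks down glutathione, fell by 1.48 ± 0.11. In all, 2218 of the 16122 genes rose and 2664 fell, 4882 in total, of which 277 changed at least 2-fold, 173 higher and 104 lower.

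Growth, lipid and signal-responsive lists were lower at 12 h, and so were G1-S genes. Of 35 MYC and nucleolar targets, 33 fell and none rose (34 fell adjusted over the list alone, median −0.51, camera adjusted p = 2.4e-42). MYC was at 103 ± 3.9 CPM against 156 ± 6.0 (−0.60 ± 0.05, edgeR adjusted p = 2.0e-10). Of 31 genes of ATF4 and the amino acid response, 27 fell and 2 rose (28 and 2 adjusted over the list alone, median −0.52, camera adjusted p = 8.3e-36). SLC7A5 was at 47.2 ± 1.4 CPM against 112 ± 2.2. In cholesterol synthesis 19 of 25 fell and none rose, also adjusted over the list alone (median −0.37, camera adjusted p = 6.9e-13), with HMGCS1 at −0.61 ± 0.05. In fatty acid synthesis 10 of 15 fell and none rose (11 and 1 adjusted over the list alone, median −0.30, camera adjusted p = 5.2e-09). SCD was at 152 ± 5.2 CPM against 280.4 ± 9.6 (−0.88 ± 0.04, edgeR adjusted p = 1.3e-14). In glycolysis and hypoxia 16 of 25 fell and none rose (19 and 1 adjusted over the list alone, median −0.19, camera adjusted p = 3.0e-08, but adjusted p = 0.12 with an estimated correlation). The lactate dehydrogenase gene LDHA was at −0.53 ± 0.05. In the immediate early and ERK response 15 of 25 fell and 3 rose (16 and 3 adjusted over the list alone, median −0.54, camera adjusted p = 2.2e-12), with EGR1 at −1.25 ± 0.10. Of 26 NF-kB targets, 15 fell and 7 rose (16 and 7 adjusted over the list alone, median −0.17, camera adjusted p = 8.3e-04, but adjusted p = 0.12 with an estimated correlation). The cytokine gene LTA was at −0.93 ± 0.07. Of 27 measured G1-S genes, 17 fell and none rose, also adjusted over the list alone (median −0.20, camera adjusted p = 7.0e-08). They fell against DMSO of the same time, while the summed CPM of the list rose from 4 h to 12 h with both treatments. CDC25A, a phosphatase that lets cells enter S phase, fell by 0.59 ± 0.07, and the replication helicase subunit MCM4 was at 200.5 ± 10.1 CPM against 270.0 ± 2.5 (−0.43 ± 0.05, edgeR adjusted p = 5.4e-08).

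FOXO targets, B cell genes and interferon genes stayed higher at 12 h. Of 26 FOXO targets, 16 rose and 1 fell, also adjusted over the list alone (median 0.40, camera adjusted p = 7.2e-18). PIK3IP1 was at 18.4 ± 1.6 CPM against 7.13 ± 0.41 (1.38 ± 0.11, edgeR adjusted p = 4.4e-10) and TXNIP at 1.41 ± 0.07. Of 19 B cell identity genes, 8 rose and 1 fell (9 and 3 adjusted over the list alone, median 0.14, camera adjusted p = 5.5e-06). PAX5, the transcription factor that maintains B cell identity, was at 465 ± 15 CPM against 336 ± 9.5 (0.47 ± 0.04, edgeR adjusted p = 5.5e-09). Of 27 measured components of B cell receptor signalling, 10 rose and 5 fell (12 and 5 adjusted over the list alone, median 0.10, camera adjusted p = 0.032). CD79A and CD79B, the signalling chains of the receptor, rose by 0.51 ± 0.05 and 0.90 ± 0.08, and PTPN6 fell by 0.64 ± 0.04. Of 30 interferon response genes, 14 rose and none fell (17 rose adjusted over the list alone, median 0.22, camera adjusted p = 2.3e-07). The antiviral GTPase gene MX1 was at 628 ± 9.4 CPM against 459 ± 5.6. Of 8 stromal and epithelial markers, 7 rose and none fell, also adjusted over the list alone (median 0.50, camera adjusted p = 1.7e-04). COL1A1 was at 26.1 ± 1.5 CPM against 14.7 ± 1.9 (0.83 ± 0.10, edgeR adjusted p = 5.1e-07).

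A further pair of lists gave a call at 12 h that an estimated correlation removed. Of 12 HLA class I genes, 6 rose and 1 fell (7 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.036, but adjusted p = 0.45 with an estimated correlation), with HLA-E at 0.29 ± 0.04. Of 40 cytosolic ribosomal protein genes, 6 rose and none fell, and 0 passed by edgeR when adjusted over the list alone (median 0.09, camera adjusted p = 0.0090, but adjusted p = 0.60 with an estimated correlation). The 11 remaining list calls at 12 h held with an estimated correlation, at adjusted p from 2.4e-05 to 0.048, but under the GC and length correction B cell receptor signalling did not (adjusted p = 0.19).

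The genes followed in every comparison included PI3K subunits, the insulin receptor and survival factors. PIK3CD, the catalytic subunit delta that predominates in B cells, was at 0.08 ± 0.05 at 4 h (edgeR adjusted p = 0.23) and rose by 0.23 ± 0.05 at 8 h and 0.25 ± 0.05 at 12 h. The alpha subunit gene PIK3CA rose by 0.60 ± 0.08 at 4 h (0.32 with replicate 3 as the only copanlisib library) and was at 0.16 ± 0.08 at 8 h (edgeR adjusted p = 0.11). At 12 h it rose by 0.22 ± 0.08 (edgeR adjusted p = 0.034), a call lost without replicate 1, 2 or 3 of DMSO (adjusted p = 0.068, 0.11 and 0.063) or replicate 2 or 3 of copanlisib (adjusted p = 0.065 and 0.18). INSR, the insulin receptor gene, rose by 0.27 ± 0.04, 0.26 ± 0.04 and 0.20 ± 0.04 at the 3 times. The cyclin gene CCND2 fell by 0.33 ± 0.04, 0.38 ± 0.04 and 0.17 ± 0.04, and MCL1 rose by 0.46 ± 0.05, 0.49 ± 0.05 and 0.54 ± 0.05. FOXO1 rose by 0.36 ± 0.06 at 4 h (0.23 with replicate 3 as the only copanlisib library) and was at 0.03 ± 0.06 and 0.05 ± 0.06 later. BCL2, IRS2 and BCL2L11, which encodes the BH3-only protein BIM, passed at none of the 3 times by edgeR. KLF2, a FOXO target below 2 CPM, rose at 8 h (1.28 ± 0.44, edgeR adjusted p = 0.026), a call lost without replicate 2 or 3 of DMSO (adjusted p = 0.098 and 0.067) or replicate 1 or 2 of copanlisib (adjusted p = 0.067 and 0.053). BCL6 had too few reads to be tested.

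Apart from markers of other cells, 7 lists gave no call by camera at any time. For PI3K-AKT-mTOR components (24 measured), 9 rose and 7 fell at 4 h, 5 and 8 at 8 h, and 6 and 5 at 12 h, by edgeR. For the BCL2 family (14 measured), 2 rose and 7 fell, then 3 and 2, then 3 and 3, and for plasma cell genes (18 measured) 7 and 7, 5 and 6, and 6 and 7. The plasma cell genes included JCHAIN, the joining chain of secreted antibody, which rose by 0.95 ± 0.06 at 12 h. Among 18 measured migration receptors 4, 8 and 7 rose and 2, 3 and 3 fell, and among 13 HLA class II genes 1, 3 and 5 rose and 3, 1 and 0 fell by edgeR. For 29 measured lysosome and autophagy genes 5, 6 and 11 rose and 6, 4 and 2 fell, and for 20 measured p53 targets 8, 6 and 5 rose and 9, 5 and 7 fell. Adjusted over the list alone, the risen and fallen counts became 9 and 8 for PI3K-AKT-mTOR components at 4 h, 3 and 4 for the BCL2 family at 8 h and 12 h, and 6 and 8 for plasma cell genes at 12 h. They became 3 and 2 for migration receptors at 4 h, 7 and 4 and then 12 and 3 for lysosome and autophagy genes at 8 h and 12 h, and 7 and 7 for p53 targets at 12 h, and stayed as given elsewhere. Camera adjusted p-values for these 7 lists lay between 0.058 and 0.98. At 4 h fry called PI3K-AKT-mTOR components and migration receptors as higher (fry adjusted p = 7.0e-06 and 3.9e-04) and the BCL2 family as lower (0.0075). Plasma cell genes, HLA class II, lysosome and autophagy genes and p53 targets did not pass by fry at 4 h (adjusted p from 0.097 to 0.37). Under the GC and length correction 10 lysosome and autophagy genes rose and 6 fell at 4 h by edgeR, and 9 and 7 p53 targets. The 4 h median of the lysosome and autophagy genes was 0.05, and −0.03 with replicate 3 as the only copanlisib library. PI3K-AKT-mTOR components (9 rose, 3 fell) and migration receptors passed at 4 h when replicate 3 was the only copanlisib library (camera adjusted p = 0.047 and 0.037, but adjusted p = 0.20 and 0.091 with an estimated correlation). A pair of lists called only at 12 h missed at 4 h and 8 h, G1-S genes (7 rose and 6 fell, then 5 and 10, camera adjusted p = 0.92 and 0.17) and components of B cell receptor signalling (10 and 5, then 11 and 3, or 11 and 5, then 12 and 5, adjusted over the list alone, camera adjusted p = 0.19 and 0.058). Under the GC and length correction B cell receptor signalling passed at 4 h and 8 h (camera adjusted p = 0.0064 and 0.049). With an estimated correlation it did not (adjusted p = 0.25 and 0.39). G2-M genes gave no call at 8 h (3 rose, 2 fell) or 12 h (2 rose, 1 fell), at camera adjusted p = 0.69 and 0.72 (1 and 1, then 0 and 0 adjusted over the list alone). B cell identity genes (11 rose, 4 fell, also adjusted over the list alone) and stromal and epithelial markers (2 rose, none fell, and 1 rose adjusted over the list alone) gave none at 4 h, at camera adjusted p = 0.070 and 0.29. With replicate 3 as the only copanlisib library these 2 lists passed at 4 h (camera adjusted p = 0.0013 and 0.048, but adjusted p = 0.083 and 0.10 with an estimated correlation). HLA class I and cytosolic ribosomal protein genes gave no call at 8 h (2 rose and 1 fell, then 1 and 0 by edgeR, camera adjusted p = 0.35 and 0.20).

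Markers of other cells were measured for few genes, and levels here are CPM without TMM scaling. T and NK cell markers (6 of 17 measured) and myeloid markers (4 of 14) gave no list call, at camera adjusted p from 0.42 to 0.99. CD3D, CD3G, TRBC1 and CD8B had no reads in the 18 libraries, but the T cell receptor constant segments TRAC and TRBC2 were at 32.4 to 43.3 and 23.6 to 49.0 CPM, and NKG7 at 7.25 to 16.4. TRBC2 rose by 0.85 ± 0.07 on the log2 scale at 12 h, and the myeloid marker VCAN was at 85.2 to 133 CPM. Retina markers (3 of 16 measured) gave no call at camera adjusted p = 0.83, 0.56 and 0.19, with PDE6B and PDE6G at 5.59 to 10.3 and 8.00 to 13.1 CPM. Of the stromal and epithelial markers, the fibroblast genes COL1A2, COL3A1 and DCN stayed at or below 0.102 CPM and LUM had no reads.

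**Figure D3:**
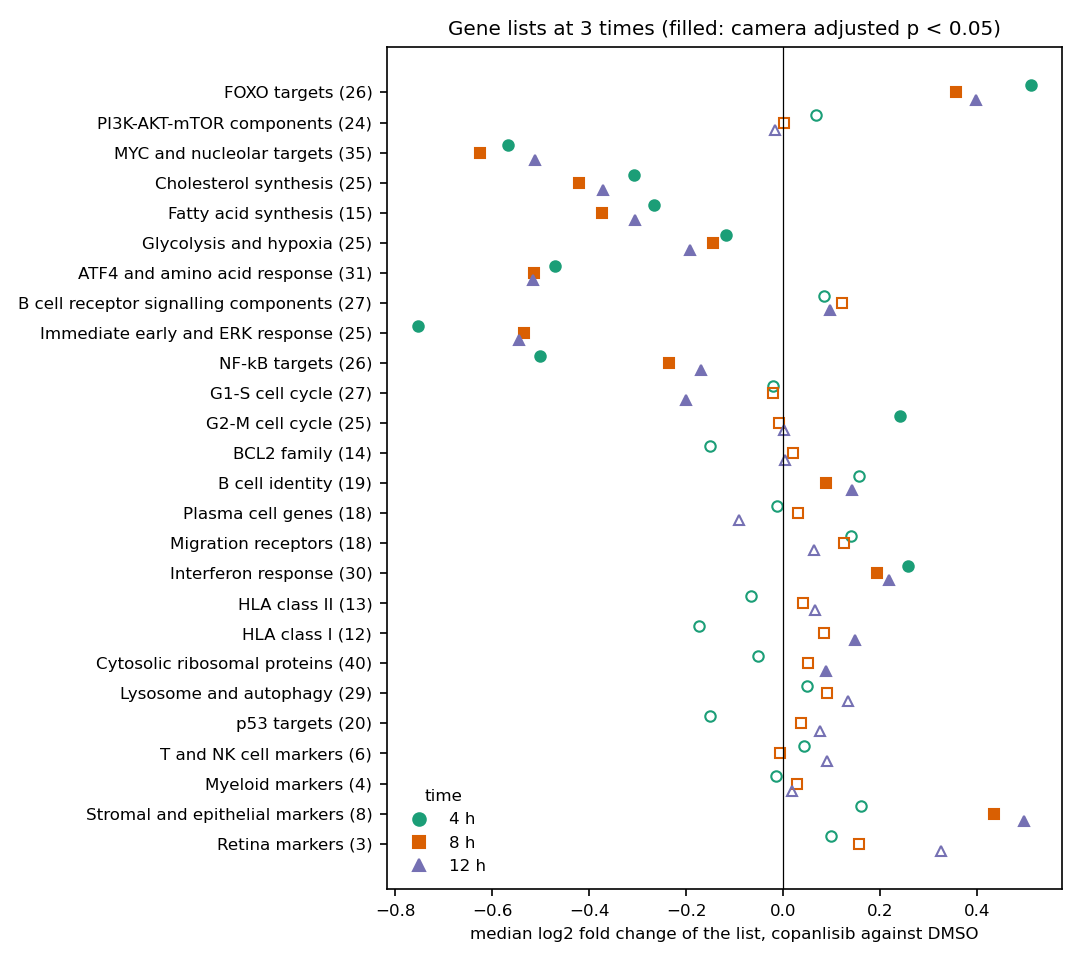
Median log2 fold change (x axis) of the measured members of each of the 26 gene lists (y axis) for copanlisib against DMSO at 4, 8 and 12 h, with filled symbols where camera gave an adjusted p below 0.05. The lowest medians are −0.75 for the immediate early and ERK response at 4 h and −0.62 for MYC and nucleolar targets at 8 h, and the highest are 0.51 for FOXO targets at 4 h and 0.50 for stromal and epithelial markers at 12 h. With replicate 3 as the only copanlisib library at 4 h, the −0.75 becomes −0.61 and the 0.51 becomes 0.36.

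For some lists the median, mean and test did not share a sign. At 4 h these were p53 targets (median −0.15, mean −0.09, camera up), plasma cell genes (−0.01, 0.01, down), G1-S genes (−0.02, 0.00, down), myeloid markers (−0.01, −0.04, up) and T and NK cell markers (0.04, −0.04, down). Under the GC and length correction the 4 h medians of p53 targets, plasma cell genes and G1-S genes were 0.01, 0.02 and 0.05. With replicate 3 as the only copanlisib library they were 0.05, 0.02 and 0.03. At 8 h they were G2-M genes (−0.01, 0.00, up), PI3K-AKT-mTOR components (0.00, −0.00, up), myeloid markers (0.03, 0.09, down) and T and NK cell markers (−0.01, −0.04, up). At 12 h they were plasma cell genes (−0.09, 0.05, up), the BCL2 family (0.00, −0.04, up) and G2-M genes (0.00, −0.00, up).

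Averaged over the 3 times, 3952 genes rose and 4127 fell with copanlisib, 8079 of 16122 in all. Each of the 35 MYC and nucleolar targets fell, 29 of 31 genes of ATF4 and the amino acid response, 23 of 25 of cholesterol synthesis and 19 of 26 NF-kB targets fell, and 20 of 26 FOXO targets and 21 of 30 interferon response genes rose. Adjusted over the list alone, 21 FOXO targets rose and the other 5 counts were the same, and camera adjusted p-values lay between 3.5e-54 and 7.3e-08. The interferon response on average had a median of 0.25, at adjusted p = 0.032 with an estimated correlation, but 0.052 when replicate 3 was the only copanlisib library at 4 h. The 8 h and 12 h comparisons share no library, and 1473 genes rose and 2080 fell in both, where independent lists of these lengths would share 329 and 486, while 2 genes changed in opposite directions. Both tests use a spread per gene estimated from all 18 libraries, so their calls are not independent. Expected counts here are a reference and not what would be shared without a common response. Across genes, which are not independent replicates, the log2 fold changes of 8 h and 12 h had a Pearson r of 0.65 and a Spearman correlation of 0.69. Against 8 h, the 4 h comparison shared 1078 risen and 1627 fallen genes (expected 424 and 609) with r at 0.49, and 89 and 80 genes changed in opposite directions. At all 3 times 804 genes rose and 1341 fell.

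Whether the response changed with time was tested on the difference of the effects. LTB, at 0.28 ± 0.11 at 4 h (edgeR adjusted p = 0.049, and 0.55 with replicate 3 as the only copanlisib library), had an effect higher at 12 h than at 4 h by 1.72 ± 0.15 on the log2 scale (SE, n = 3 per group, edgeR adjusted p = 9.4e-08). SPIB, a transcription factor of B cells, fell by 0.63 ± 0.06 at 4 h and rose by 0.51 ± 0.06 at 12 h, a difference of 1.14 ± 0.09 (edgeR adjusted p = 2.5e-08). For PIK3CG the difference was −0.94 ± 0.13 and for ANK2, an ankyrin, −1.06 ± 0.14. When replicate 3 was the only copanlisib library at 4 h, these 4 differences were 1.45, 0.98, −0.87 and −0.98. For 16 of 26 NF-kB targets the effect was higher at 12 h than at 4 h and for no gene lower (17 adjusted over the list alone, median difference 0.30, camera adjusted p = 6.2e-17, and adjusted p = 0.0057 with an estimated correlation). For 13 of 27 G1-S genes the effect was lower at 12 h and for 1 higher (14 and 1 adjusted over the list alone, median −0.29, camera adjusted p = 4.2e-07, but adjusted p = 0.11 with an estimated correlation). From 4 h to 12 h the summed CPM of the G1-S list, without TMM scaling, rose with both treatments. It went from 3201, 3175 and 3181 to 4145, 4172 and 4192 with DMSO. With copanlisib it went from 2991, 3036 and 3169 to 3766, 3678 and 3622.5, a smaller rise. With replicate 3 as the only copanlisib library at 4 h the G1-S median was −0.26, at an adjusted p of 0.047 with an estimated correlation. In all, the effect differed between the 3 times for 2996 genes and between 4 h and 12 h for 2688, higher at 12 h for 1448 and lower for 1240. With replicate 3 as the only copanlisib library at 4 h, 952 and 900 genes passed. Leaving out replicate 2 of copanlisib at 4 h gave 1551 and 1596 genes, replicate 1 gave 1801 and 1741, and replicate 3 gave 6557 and 5781. Without replicate 3 of DMSO at 4 h the counts were 1595 and 1687, and without replicate 1 of DMSO at 12 h 1742 genes differed between 4 h and 12 h. The difference between 12 h and 4 h itself followed GC content, with a Spearman correlation of 0.51 across 16004 genes. For the effects at 4, 8 and 12 h this correlation was −0.36, 0.20 and 0.13, and 0.04 at 4 h with replicate 3 as the only copanlisib library. The counts above therefore include genes that differ along this GC trend.

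The DMSO libraries show how far the cells moved without the drug. From 4 h to 12 h, CXCL10, an interferon-induced chemokine, rose from 301 ± 5.7 to 952 ± 41.6 CPM (SD, n = 3 each), a log2 fold change of 1.66 ± 0.06 (edgeR adjusted p = 6.0e-17). HSPA6, an inducible HSP70 chaperone, fell from 55.2 ± 1.7 to 8.96 ± 0.73 CPM (−2.62 ± 0.09, edgeR adjusted p = 8.6e-18), and BNIP3, a mitophagy receptor induced by hypoxia, fell from 53.1 ± 4.9 to 12.0 ± 0.9 CPM (−2.15 ± 0.09). The glycolysis regulator PFKFB4 fell by 2.32 ± 0.14, and MXI1, which encodes a MYC antagonist, by 2.49 ± 0.11. Of 30 interferon response genes, 27 rose and 2 fell (28 and 2 adjusted over the list alone, median 0.66, camera adjusted p = 2.6e-17), and of 27 G1-S genes 24 rose and 1 fell, also adjusted over the list alone (median 0.59, camera adjusted p = 4.6e-18). Of 25 genes of glycolysis and hypoxia, 23 fell and none rose (23 and 1 adjusted over the list alone, median −0.72, camera adjusted p = 9.5e-33). Lower medians also held for MYC and nucleolar targets (4 rose, 23 fell, −0.33), ATF4 and the amino acid response (5 rose, 18 fell, −0.30), the immediate early and ERK response (2 rose, 14 fell, −0.27) and NF-kB targets (3 rose, 18 fell, −0.35), at camera adjusted p from 2.4e-06 to 2.2e-05. Adjusted over the list alone these 4 lists had 5 risen and 23 fallen, 6 and 19, 3 and 16, and 4 and 18 genes. The NF-kB call was lost at adjusted p = 0.052 with an estimated correlation (0.021 under the GC and length correction), and the other 6 lists named here held. Camera also gave calls in DMSO for components of B cell receptor signalling (15 rose, 8 fell, adjusted p = 0.0028) and plasma cell genes (4 rose, 9 fell, adjusted p = 0.018). With an estimated correlation and the GC and length correction neither passed (adjusted p = 0.16 and 0.060). Calls for cholesterol synthesis (5 rose, 14 fell), HLA class II (2 rose, 7 fell) and the BCL2 family (2 rose, 6 fell) were lost at adjusted p = 0.13, 0.22 and 0.13 with an estimated correlation. The test of 8 h and 12 h against 4 h together found 8373 genes changed over time in DMSO, and 12 h against 4 h found 3744 risen and 4093 fallen.

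Positions are those of GENCODE 29 on GRCh38 for the gene bodies. XCL1 (ENSG00000143184) lies on chromosome 1 from 168576473 to 168582077, EGR1 (ENSG00000120738) on chromosome 5 from 138465490 to 138469315, and HMGCS1 (ENSG00000112972) on chromosome 5 from 43289395 to 43313512. MYC (ENSG00000136997) lies on chromosome 8 from 127735434 to 127741434, TP53INP1 (ENSG00000164938) on chromosome 8 from 94925972 to 94949411, and SLC7A5 (ENSG00000103257) on chromosome 16 from 87830023 to 87869488. LTB (ENSG00000227507) lies on chromosome 6 from 31580525 to 31582522, PIK3IP1 (ENSG00000100100) on chromosome 22 from 31281593 to 31292534, and PIM2 (ENSG00000102096) on chromosome X from 48913182 to 48919024. The files give 1 value per gene, so isoforms are not separated.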

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

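The tests of GC content and length, of read numbers, of the NF-kB list's change in DMSO and of other cells' genes were chosen only after the results were seen, as was the fit with replicate 3 as the only copanlisib library at 4 h.

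Replicates 1 and 2 of copanlisib at 4 h differed from the other libraries in data outside the gene counts: 8.73% and 5.22% of their reads were unmapped (DMSO maximum 2.52%), and 5.67% of strand-assigned reads in replicate 1 lay on the minor strand (DMSO maximum 4.84%). That these libraries came mostly from untreated cells is argued against by 3553 genes changed the same way at 8 h and 12 h. Over these genes replicates 1 and 2 had slopes of 0.627 and 0.654 against the mean later effect (DMSO libraries −0.04 to 0.03). Replicate 3 had a higher slope of 0.727, so a smaller share of untreated cells in replicates 1 and 2 stays open. Fewer reads are argued against as well, with 20.7 M gene reads in the smaller of the pair and 18.7 M in replicate 3. A curve on GC content and transcript length explained 33.9% of the variance across genes of the difference from replicate 3, so a bias of library preparation or sequencing may account for part of it and leaves the rest open. No biological explanation was tested, since the labels give these libraries no other condition.

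The difference of the copanlisib effect between times was tested directly, and NF-kB targets fell less at 12 h than at 4 h, with a median difference of 0.30. The GC trend of the 4 h libraries is argued against as the whole cause: with the GC and length correction or with replicate 3 as the only copanlisib library the list stayed past the threshold, and the smaller of the 2 median differences was 0.23. A fall in the DMSO cells themselves went with the pattern: from 4 h to 12 h the list's median changed by −0.35 in DMSO (3 rose, 18 fell, camera adjusted p = 0.052 with an estimated correlation) and by 0.086 in copanlisib libraries (11 rose, 6 fell), or by −0.0040 there (6 rose, 6 fell) with replicate 3 alone at 4 h. A candidate explanation is therefore that NF-kB target expression declined in untreated culture while copanlisib had lowered it already by 4 h. This is a hypothesis found and tested on the same libraries, and a waning of the drug's effect stays open beside it.

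The effect on stromal and epithelial markers was higher at 12 h than at 4 h by a median of 0.35 (camera adjusted p = 0.036, adjusted p = 0.17 with an estimated correlation, and adjusted p = 0.10 with replicate 3 as the only copanlisib library at 4 h), and the list rose at 8 h and 12 h. Cells that express COL1A2, COL3A1, DCN, LUM or KRT19 are argued against as the source. In copanlisib libraries of 8 h and 12 h the first 4 of these genes together came to at most 0.336% of COL1A1, and KRT19 to 0% of KRT18, and the labels name no sort. The test was set after the data were seen, and cells of a type without these genes were not tested. A rise of all genes at this low level is argued against, because the list's 12 h median of 0.50 lay at percentile 99.97 of 10000 random lists of the same size matched on expression. The list was taken up because it rose in these libraries, and the random members were drawn independently of each other. The percentile therefore speaks to the expression level and does not measure chance. What remains open is a change of the listed markers in the lymphoma cells, which is a hypothesis, or cells of a type not tested here. Only 8 of 14 markers were measured.

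By edgeR the copanlisib effect differed between the 3 times for 2996 genes and between 4 h and 12 h for 2688. Across genes the difference between 12 h and 4 h had a Spearman correlation of 0.51 with GC content. Leaving out replicate 1, 2 or 3 of copanlisib at 4 h gave 1801, 1551 and 6557 genes for the 3 times and 1741, 1596 and 5781 for 4 h against 12 h, and leaving out replicate 3 of DMSO at 4 h gave 1595 and 1687, and replicate 1 of DMSO at 12 h 1742 for 4 h against 12 h. Splits that exchange DMSO and copanlisib within the times ask whether the drug had an effect, not whether it was equal at each time, so they leave open whether chance can be excluded here. The highest other split gave 4528 and 5481 genes, and it exchanged 3 libraries of each treatment at 4 h and 1 of each at 8 h.

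Other lists whose effect differed between 12 h and 4 h by camera lost the call with an estimated correlation when all 18 libraries were used without a GC correction. The immediate early and ERK response differed by a median of 0.34 (camera adjusted p = 7.0e-04, adjusted p = 0.12 with an estimated correlation). G1-S genes differed by −0.29 (4.2e-07 and 0.11), and with an estimated correlation they passed under the GC and length correction (−0.29, adjusted p = 0.00998) and with replicate 3 alone at 4 h (−0.26, adjusted p = 0.047). G2-M genes differed by −0.20 (8.6e-05 and 0.26), and by −0.077 with replicate 3 alone. B cell identity genes differed by 0.034 (adjusted p = 0.033 and 0.12). HLA class II differed by 0.12 (adjusted p = 0.011 and 0.36), HLA class I by 0.23 (3.7e-05 and 0.26) and cytosolic ribosomal proteins by 0.13 (2.4e-05 and 0.60). In the fit with replicate 3 alone at 4 h, HLA class II no longer passed with the preset correlation (adjusted p = 0.10), and 0 HLA class I genes passed by edgeR against 7, at a median of 0.11. In that fit 1 cytosolic ribosomal protein gene passed by edgeR against 11.

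Among single genes the effect was higher at 12 h than at 4 h for LTB by 1.72 ± 0.15, SPIB by 1.14 ± 0.09, KREMEN2 by 1.10 ± 0.18, METRN by 0.95 ± 0.19 and DUSP2 by 0.95 ± 0.15 (log2 ± SE, edgeR adjusted p from 2.5e-08 to 0.0014). It was lower for ANK2 at −1.06 ± 0.14, FAM111B at −0.99 ± 0.18, TENM1 at −0.97 ± 0.18, BRCA2 at −0.97 ± 0.18 and PIK3CG at −0.94 ± 0.13 (edgeR adjusted p from 2.3e-05 to 8.0e-04). In that fit with replicate 3 alone METRN was at 0.49 and did not pass (edgeR adjusted p = 0.10), and DUSP2 and KREMEN2 were at 0.51 and 0.60. Groups of 3 libraries were not tested for single libraries far from the others.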

How the results depend on the processing

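Tests with the GC and length correction and with replicate 3 as the only copanlisib library at 4 h were chosen only after the results were seen. Counts of genes stayed within 1.5 times in 123 of 141 recomputed values, which compares their size and not which genes passed. The 4 h count went from 6195 to 3733 with only the 6 libraries of that time and to 3778 with replicate 3 alone. The effect that differs between the 3 times went from 2996 to 952 genes with replicate 3 alone, to 1231 at an adjusted p under 0.01 and to 1551 to 6557 with a library left out. The 4 h against 12 h difference went from 2688 to 900 and 1134 at the same settings and to 1596 to 5781 with a library left out. With only the 6 libraries of their time, 7020 genes passed at 8 h and 6262 at 12 h, against 5336 and 4882. Which time has the most changed genes therefore depends on whether the spread is shared between times. Fewer copanlisib libraries at 4 h or a stricter threshold are part of some of the other settings, and beyond that the cause was not tested. A log2 fold change of at least 1 left 352, 235 and 277 genes at 4, 8 and 12 h by construction. The GC and length correction gave 6485 genes at 4 h, of which 4793 were among the 6195. For the difference between the 3 times it gave 2252 genes, of which 1421 were among the 2996. For 4 h against 12 h it gave 2293, of which 1441 were among the 2688, so many of the called genes changed. With a library left out the 4 h count ran from 4903 to 7857, the 8 h count from 4312 to 4501 and the 12 h count from 3909 to 4135.

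With the replicate number as a block (replicate block) 6206, 5301 and 4887 genes passed at the 3 times and 8126 on average, and the block changed no call among the lists and 1 among the named genes (WIPI1 at 8 h). Libraries that share a number and a time correlated by −0.034 to 0.101 in their deviations, and 7 of 18 libraries correlated best with their own number. No pairing by number was detected, and the labels do not say whether equal numbers belong together. Of the results of named genes 4909 stayed on the same side of the threshold, called or not, 218 lost a call and 13 gained one. Another 3 changed sign, to values near 0, all 3 with replicate 3 alone at 4 h. These were HLA-C at 0.022, HLA-DQB1 at 0.0045 and RPL13 at 0.0056, and the cause was not tested. Leaving out 1 library accounts for 147 of the 218. Of the list results 495 stayed on the same side of the threshold, called or not. A call was lost in 25 (21 with an estimated correlation) and gained in 52 (31 with fry). Over 26 lists and 3 times the calls numbered 36 by camera, 27 with an estimated correlation, 53 by fry and 41 with the GC and length correction. Effects of genes with few reads are less certain, such as KLF2, whose SE at 8 h was 0.44, and the part of depth in this was not tested.

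As to chance, the splits at each time are too few for a share under 0.05: 6195 genes at 4 h against 1161 in the highest other split, 5336 against 0 at 8 h and 4882 against 0 at 12 h by edgeR. The 4 h split with 1161 genes parted replicates 1 and 2 of copanlisib and replicate 1 of DMSO from the rest. For the average only the real split of 100 gave as many genes (8079 against 461), and so it was for time in DMSO (8373 against 4853). This argues against chance in the spread between libraries. The labels do not say that libraries came from separate cultures, so chance differences between cultures cannot be excluded by exchanging libraries.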

Other observations

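The gene groups here were drawn up by family name, and their tests and members chosen, only after the results were seen, while the test along time in culture was fixed before. In all, 14 groups were tested, and p-values are adjusted over them within each comparison. With an estimated correlation mitochondrial ribosomal proteins (adjusted p = 0.31, 0.20 and 0.34), respiratory chain subunits (0.66, 0.94 and 0.91), ZNF zinc finger proteins (0.25, 0.43 and 0.32) and translation initiation factors (0.37, 0.055 and 0.13) gave no call at 4, 8 or 12 h. Small nucleolar RNA host genes (0.026, 0.20 and 0.17) and solute carriers (0.017, 0.20 and 0.10) were called, as lower, at 4 h and not later. The group drawn for RNA polymerase I held a transcript that is not a subunit, and its values are not used.

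Subunits of the transcription and folding machinery were lower with copanlisib. Of 10 measured subunits of RNA polymerase III, 6, 7 and 6 fell at 4, 8 and 12 h and none rose, with median log2 fold changes of −0.36, −0.29 and −0.30 (camera with an estimated correlation, adjusted p = 0.0094, 0.0047 and 0.013). POLR3G fell by 0.81 ± 0.09, 1.29 ± 0.09 and 1.16 ± 0.10 (SE, n = 3 per group). Of the 8 subunits of the chaperonin CCT, which folds actin and tubulin, 7 fell at 4 h and all 8 at 8 h and 12 h, with medians of −0.23, −0.40 and −0.33 (adjusted p = 0.083, 0.0047 and 0.013 with an estimated correlation). Of 37 genes with the symbols of proteasome core and cap subunits, 24, 21 and 17 fell and 0, 0 and 1 rose by edgeR, but the adjusted p with an estimated correlation was 0.21, 0.087 and 0.13.

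Among 18 measured chemokine ligands, 9, 8 and 9 fell and 2, 2 and 3 rose at the 3 times (adjusted p = 0.0094, 0.047 and 0.013 with an estimated correlation). Their medians were −0.51, −0.04 and −0.39, so at 8 h the group's median was near 0. The group counts XCL1 and XCL2, CCL3 and CCL3L3, and CCL4 and CCL4L2 as separate members, although these are near-identical copies. CCL3, CCL4 and CCL22 are also in the list of NF-kB targets, so the group's result is not independent of that list. The fallen ones included CCL20 at −1.12 ± 0.18, −1.25 ± 0.18 and −1.69 ± 0.20, and CXCL8 fell too, at −1.16, −1.08 and −1.45. CXCL9 and CXCL10, which interferon induces, rose at each time, by 0.48, 0.48 and 0.45 and by 0.77, 0.55 and 0.40. Of 6 guanylate-binding protein genes, also induced by interferon, 5, 4 and 5 rose (adjusted p = 0.043, 0.16 and 0.10 with an estimated correlation), while GBP1 was at −0.18, −0.27 and −0.33. Of 20 genes with the symbols of dual-specificity phosphatases, only a part of which act on MAP kinases, 11, 9 and 7 fell and 2, 2 and 4 rose (adjusted p = 0.0030, 0.055 and 0.13 with an estimated correlation). The 13 protein genes of the mitochondrial genome moved with the replicates that stood apart: 12 rose at 4 h (median 0.30, adjusted p = 0.21 with an estimated correlation).

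One hypothesis was that copanlisib brings forward the change that DMSO cells show from 4 h to 12 h. Across genes, the Pearson r between the 8 h effect and that change, which share no library, was 0.136 (Spearman 0.176). This lies between the bound of 0.3 set for the hypothesis and the bound of 0.1 set against it, so it cannot be told apart from no relation of that kind by this test. Of the genes called in both, 845 were higher and 1342 lower in both, where 555 and 747 would be shared by independent lists, and 418 and 570 went opposite ways (expected 607 and 684). Since both tests share the spread estimated per gene, these lists are not independent.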
